A study of Mus musculus with 6 samples.

How the data were processed

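RNA was measured in whole lungs of 6 male BALB/c mice, 3 kept in normal air and 3 kept for 3 weeks in air with 2% hydrogen. Per the labels' protocols, lungs were held in RNAlater, total RNA was isolated with a column kit, and amplified biotin-labelled antisense RNA was hybridised to MG-430 PM Array Strips on the Affymetrix GeneAtlas system. The deposited table holds log2 values of each probe set on each array, to 2 decimals; per the submitters' processing notes the tools were RMA and Affymetrix Expression Console. The versions, and whether all 6 arrays were normalised in a single run, are not given in the sources used here. No scanner files, genome or coordinates were used here. The medians of the arrays were 4.75 to 4.85 on the log2 scale. Precision is limited by the number of arrays: 3 mice per group, each measured on 1 array. Each mouse is a replicate, as the series' design counts the mice.

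Of 45141 probe sets, 104 are control probe sets by name and 45037 entered the tests. The platform annotation given for this work names 1 gene for 28898 probe sets, several for 551 and none for 15588. The latter kinds were tested as probe sets but named no gene. Symbols were checked through Entrez identifiers against RefSeq names of GRCm38.p6: 28689 of the single-gene probe sets matched and 0 symbols needed an update. A gene was represented by its probe set with the highest mean over all arrays, which gave 17097 genes. Among the named genes, 12 had a further probe set past the threshold in the opposite direction (Col14a1, Hspb1, Mb, Myh11, Nr4a2, Plet1, Plod1, Psmd4, Sc5d, Sod2, Synpo2 and Top2a).

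Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend), on the deposited log2 values without further filtering, with Benjamini-Hochberg adjustment over all genes or over all probe sets. Fold changes are hydrogen minus control, with moderated standard errors. Control probe sets were tested in a fit with all probe sets. The tests, 56 gene lists (28 pathways and 28 cell types) and the rule for named genes were fixed before the data were examined. The lists had 1364 entries, of which 1188 were measured. Each list of at least 5 measured genes was tested with camera against all other genes, with a preset correlation of 0.01. Camera was also run with an estimated correlation and on ranks, and fry was run, which asks whether a list's genes move one way without comparing them with other genes. The hydrogen group was compared with the control group and no other comparison was implied.

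The rule for named genes took the 10 largest fold changes in each direction among genes past the threshold without overlap between the groups, 4 members of each called list with the smallest p on the side of the call, 1 member of each other list, and a preset series of genes (Hmox1, Nqo1, Sod2, Cat, Fos, Dbp, Sftpc, Scgb1a1, Col1a1, S100a8, Cd79a and a beta globin, where measured). Had fewer than 10 genes qualified in a direction, genes of at least 1.4-fold would have filled the places. Clone-type symbols were not named among the largest changes. The rule named 153 genes. Per2, Myl7, Car3 and Fabp4, named in the closing section, and Myl2, Gata4, Nkx2-5, Foxm1, Plk1, Uhrf1 and Aurka fall outside it.

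Other settings chosen beforehand were a replicate block, centring on the median, renewed quantile normalisation, array weights, a prior variance with trend and robust fitting, leaving out dim rows, the mean of all probe sets of a gene, leaving out shared probe sets, and leaving out each array in turn. Cyclic loess over the 6 arrays and a comparison with 10000 random lists matched on 20 bins of brightness were added after the dependence on brightness was seen. The smallest p those random lists can give is 0.0002. Their genes were drawn independently, so that p takes no account of genes that vary together or of the spread between mice. On simulated arrays with 17097 genes, the spread of the real genes and 200 changed genes, limma recovered 80% of 100 genes changed by 0.5 and 99% of 100 genes changed by 1 on the log2 scale, with 8 of 16878 unchanged genes called, and camera called the 1 list that was raised and 0 others. The simulated genes varied independently of each other, so this could not test false calls of lists whose genes vary together. Unchanged genes had the same simulated mean in both groups. False calls from a group-wide shift or a brightness trend were therefore not tested either. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.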

Results

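Lung transcripts were measured in 6 male BALB/c mice, aged 10 weeks at the start. The control group of 3 mice breathed normal air. The hydrogen group of 3 mice breathed air with 2% molecular hydrogen, a gas studied for effects on oxidative stress, for 3 weeks. RNA from each lung was hybridised to its own oligonucleotide array, which carried 45037 probe sets besides its control probe sets. The number of arrays limits the precision of every value below. An exact permutation of 3 against 3 arrays cannot give a two-sided p below 0.1, so tests of single genes rest on limma, which shares information on the spread across genes. The design asks which genes differ in the lung after the hydrogen exposure.

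Heart muscle genes, airway secretory genes, mitochondrial respiratory chain genes, xenobiotic-metabolising enzymes, heat shock genes and glucocorticoid-induced genes were lower in the hydrogen group. T cell markers were higher. Neither the heat shock nor the T cell list passed against random lists of like brightness (adjusted p = 0.0679 and 0.358), while the others did (0.00224 to 0.0252). All of these lists were called by camera with its preset correlation and none with an estimated correlation, where their values ran from adjusted p = 0.518 to 0.567. With the preset correlation camera called 25 lists in all, and 5 to 24 lists in the 9 other splits of the 6 arrays. The natriuretic peptide gene Nppa had the largest fall next to the airway secretory gene Bpifa1, with log2 values of 9.30 ± 0.58 in controls and 4.97 ± 1.55 in the hydrogen group (SD, n = 3). Most changes were far smaller: the median absolute log2 fold change over all genes was 0.20. The labels give no batch, and control probe sets of non-mouse origin differed between the groups too. These differences therefore cannot be told apart from a difference between batches.

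Of 17097 genes tested, 4454 were higher and 4516 lower in the hydrogen group at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), 52.5% of all genes. When the arrays were quantile normalised again the split was 3948 higher and 2511 lower. At an unadjusted p under 0.05 there were 10118 genes, against 854.9 expected by chance, with 5072 higher and 5046 lower, or 4953 and 3240 after renewed quantile normalisation. A change of at least 1.5-fold with an unadjusted p under 0.05 was found for 415 genes upward and 709 downward, which turned to 492 upward and 425 downward after renewed quantile normalisation and was 412 and 468 after cyclic loess. Of the 45037 probe sets, 10956 were higher and 10257 lower. The values of the groups did not overlap for 61.0% of genes, where chance gives 10%. The arrays correlated at r = 0.995 to 0.997 over genes within a group and 0.980 to 0.988 between groups. The mean squared difference between arrays of different groups was 4.72 times that within groups, the highest of the 10 ways to split 6 arrays (exact permutation p = 0.1), with 0.984 as the next highest.

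Control probe sets that match no mouse gene differed between the groups as well. Of 85 such probe sets, 15 were higher and 27 lower at an adjusted p under 0.05 in limma, 49.4% in all. Of the 18 bacterial bio and phage cre hybridisation controls, 13 were lower, with a median log2 fold change of -0.40 over all 18 and a lowest value of -0.97. All that passed were bio probe sets. The cre probe sets, the brightest of the class, had changes from -0.13 to 0.003 and none passed. Of the nonspecific probe sets, which are grouped by their number of G and C bases, 9 of 23 were higher, up to 1.07 for probes with 25 such bases. The bacterial controls dap, lys, phe, thr and trpn were lower in 14 of 27 cases, with a median of -0.25. Of the control probe sets for mouse transcripts, those for 18S ribosomal RNA were lower at the 3' end (-0.95), in the middle (-0.83) and at the 5' end (-0.48). Pyruvate carboxylase was lower at its 3' end (-0.24) and higher at its 5' end (0.59), while none of the beta-actin probe sets passed the threshold. Gapdh was lower at the 3' end (-0.23), in the middle (-0.31) and at the 5' end (-0.39). Fold changes of mouse genes were not checked for GC content, since probe sequences were not used here. Among mouse genes past the threshold, 11 rose and 94 fell by more than the largest shift of a control probe set of non-mouse origin. The 94 included 17 cardiac muscle markers, 6 skeletal muscle markers and 5 club cell markers.

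**Figure D1:**
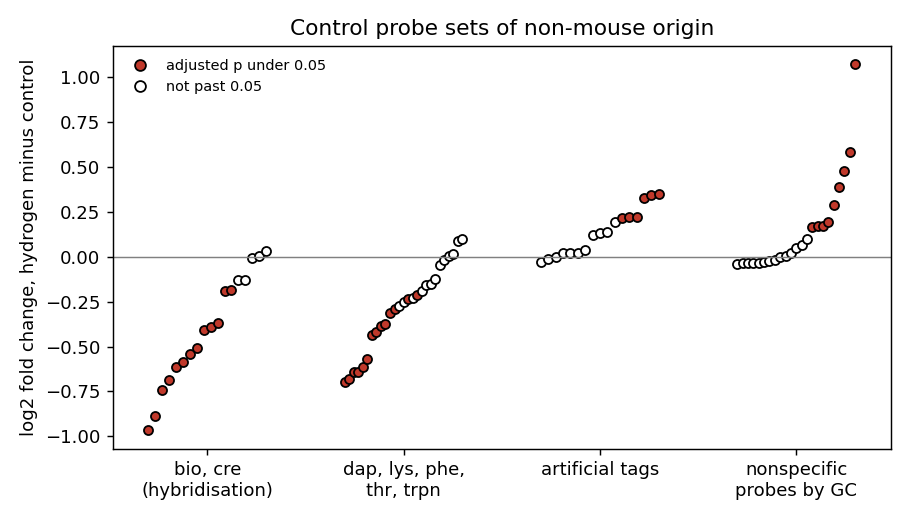
Log2 fold change (hydrogen minus control) of each control probe set of non-mouse origin, by class, sorted within each class; each point is a probe set, filled where the adjusted p was under 0.05. The bio controls reached -0.97, no cre control passed, and the nonspecific probe sets reached 1.07.

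The direction of change followed the brightness of the gene. The median log2 fold change was 0.21 in the third decile of mean log2 value and -0.22 in the eighth. Among dim genes, those at or below the median probe set, 2645 were higher and 343 lower, while among the brighter genes 1809 were higher and 4173 lower. The hydrogen arrays had a narrower range of values: their SD over probe sets was 1.80 to 1.81, against 1.90 to 1.92 in the controls.

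**Figure D2:**
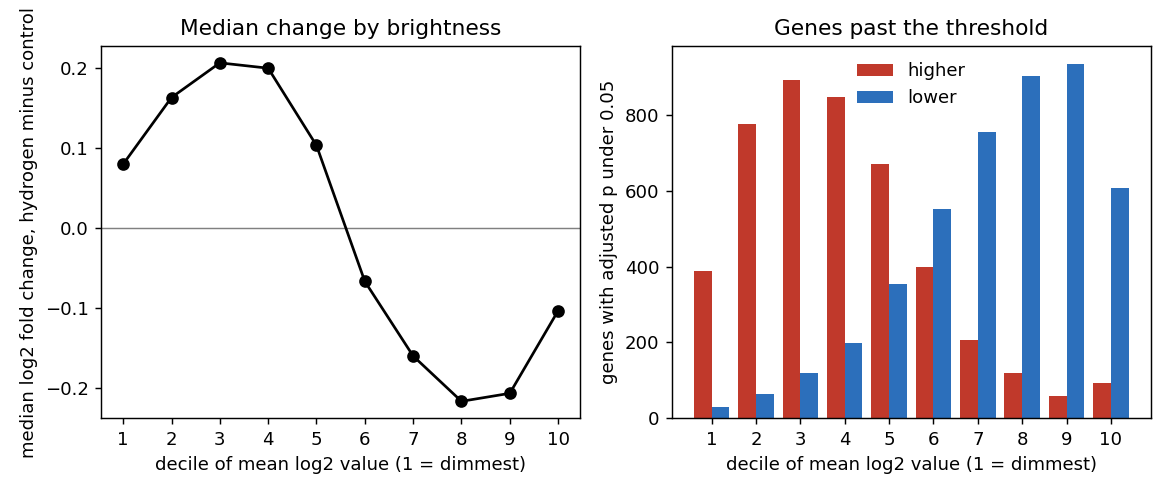
Left, median log2 fold change (hydrogen minus control) in each decile of the mean log2 value over all arrays; right, the number of genes in each decile with an adjusted p under 0.05, higher or lower in the hydrogen group. The median went from 0.08 in the dimmest decile to 0.21 in the third and -0.22 in the eighth.

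Cardiac muscle markers fell in the hydrogen group. Of the 22 measured, 18 fell, 3 rose and 1 did not pass the threshold (3 rose and 18 fell when adjusted over the list alone; median log2 fold change -1.63, adjusted p = 0.0026, and adjusted p = 0.567 with an estimated correlation). The atrial peptide gene Nppa fell by 4.33 on the log2 scale (SE 0.65, limma adjusted p = 0.00114). Of its hydrogen values (6.75, 3.96 and 4.19), 3.96 and 4.19 lay below the median probe set of 4.80, so low signal limits this estimate. Genes of the sarcomere and of calcium release fell less, among them the Z-disc genes Actn2 (-1.91) and Ldb3 (-1.63) and the calcium channel gene Ryr2 (-1.63). The cardiac transcription factor gene Tbx20 (-1.32), measured by a dim probe set, fell too. The 3 that rose, named after their values were seen, were the ventricular myosin gene Myl2 (0.36) and the cardiac transcription factor genes Gata4 (0.33) and Nkx2-5 (0.30). Their control means were low (3.77, 4.72 and 5.18), and the brightness deciles holding them had median changes of 0.16, 0.20 and 0.10. After cyclic loess the 3 genes had 0.24, 0.22 and 0.27. With the mean of all probe sets of a gene Ldb3 was -1.06, Ryr2 -0.80, Tbx20 -0.41 and Mb -1.01. The list was not past the threshold in fry (adjusted p = 0.0579). Muscle metabolism genes outside this list were among the largest falls: Ckmt2 (log2 fold change -2.77, SE 0.45, adjusted p = 0.00151), the mitochondrial creatine kinase, Mb (-2.44), which encodes myoglobin, and Pgam2 (-2.43), the muscle phosphoglycerate mutase. A further probe set of Mb changed the opposite way. The fall differed between hydrogen mice, with list medians of -1.01, -2.45 and -1.29 against the control mean in replicates 1, 2 and 3. Of the 23 skeletal muscle markers, 10 rose and 6 fell (11 rose and 6 fell when adjusted over the list alone), and the list was not called (adjusted p = 0.36), with a median of 0.15 and a mean of -0.22. Of the 23, 15 were dim, as were most of those that rose. The 6 that fell were brighter than the median probe set, with changes from -1.08 (Tcap) to -2.43 (Pgam2).

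Airway secretory genes fell. Of 15 club cell markers, 10 fell, none rose and 5 did not pass (0 rose and 10 fell when adjusted over the list alone; median log2 fold change -0.31, adjusted p = 0.0147, and adjusted p = 0.567 with an estimated correlation). The largest falls in the list were those of Bpifa1 (log2 fold change -4.44, SE 1.32, adjusted p = 0.0212), the antimicrobial gene Reg3g (-2.64), Scgb3a1 (log2 fold change -2.55, SE 0.89, adjusted p = 0.0398) and Bpifb1 (log2 fold change -2.27, SE 0.31, adjusted p = 0.000802), followed by the gel-forming mucin gene Muc5b (-1.21). The antimicrobial gene Ltf (-2.68), outside the list, fell as well. The list was not called without dim rows (adjusted p = 0.162). Bpifa1 was 10.65, 4.01 and 7.88 in hydrogen replicates 1, 2 and 3, against 11.95 ± 0.13 in controls (SD, n = 3). Its call ended without control replicate 1 or 2 (adjusted p = 0.0564 and 0.0562), and that of Scgb3a1 without control replicate 1, 2 or 3 (0.0905, 0.0982 and 0.074) and after cyclic loess (0.0584) or renewed quantile normalisation (0.0528). With a trend and robust fitting in the prior variance Bpifa1, Reg3g and Scgb3a1 were not past the threshold (adjusted p = 0.119, 0.0825 and 0.167). Without hydrogen replicate 2 the log2 fold changes of Bpifa1 and Scgb3a1 were -2.69 and -1.26. The abundant club cell gene Scgb1a1 had a log2 fold change of 0.01 (adjusted p = 0.842) at a level of 13.22, near the top of the scale, and -0.08 after cyclic loess. Of 17 ciliated cell markers, 9 fell and 1 rose (1 rose and 9 fell when adjusted over the list alone; median log2 fold change -0.24, adjusted p = 0.0297, and adjusted p = 0.568 with an estimated correlation), among them Ccdc39 (-1.14), Ccdc153 (-0.84) and the ciliary transcription factor gene Foxj1 (-0.58). Ccdc39 was -0.14 without shared probe sets (adjusted p = 0.185), where the ciliated list was not called (median -0.14, adjusted p = 0.0786), nor was it without dim rows (median -0.40, adjusted p = 0.162), in fry (0.061) or against random lists of like brightness (0.0611).

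**Figure D3:**
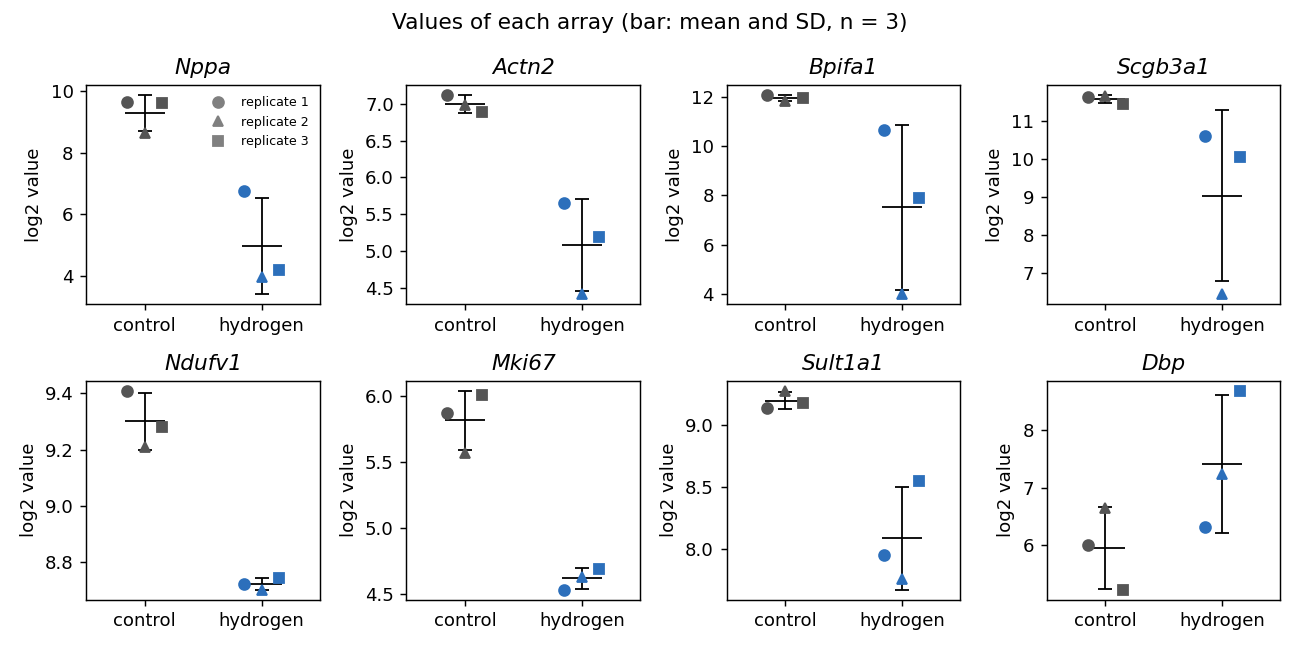
Log2 values of 8 genes in each array (points, shaped by replicate number, which is not known to pair the mice), with the mean and SD of each group (n = 3). Nppa, Actn2, Bpifa1 and Scgb3a1 were lowest in hydrogen replicate 2, where Bpifa1 was 4.01, and Ndufv1 and Mki67 were lower in all 3 hydrogen arrays than in every control array.

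Many genes of oxidative phosphorylation and xenobiotic metabolism fell by small amounts. Of 47 nuclear-encoded subunits of oxidative phosphorylation, 33 fell, none rose and 14 did not pass (0 rose and 33 fell when adjusted over the list alone; median log2 fold change -0.30, adjusted p = 5.59e-07, and adjusted p = 0.567 with an estimated correlation). Examples were the complex I genes Ndufv1 (log2 fold change -0.58, SE 0.06, adjusted p = 0.000378), Ndufa6 (-0.50) and Ndufb9 (-0.47) and the complex III gene Cyc1 (-0.54). Ndufv1 was -0.10 without shared probe sets (adjusted p = 0.165). The list median was -0.17 after cyclic loess (adjusted p = 0.000567), -0.16 after renewed quantile normalisation and -0.18 with the mean of all probe sets, and the cardiac muscle list fell with it (median -1.63). Of 24 genes of xenobiotic metabolism, 18 fell and 1 rose (1 rose and 18 fell when adjusted over the list alone; median log2 fold change -0.41, adjusted p = 0.000333, and adjusted p = 0.518 with an estimated correlation). They included the flavin monooxygenase gene Fmo1 (log2 fold change -0.51, SE 0.05, adjusted p = 0.000333), the aldehyde oxidase gene Aox3 (-0.41), the glutathione transferase gene Gstt1 (-0.50) and the carboxylesterase gene Ces1d (-0.43). The sulfotransferase gene Sult1d1 (-2.37) was among the 10 largest falls of genes past the threshold without overlap between the groups. Aox3 was -0.24 after cyclic loess. The club cell list, which shared 4 members with the xenobiotic list, fell with it (median -0.31). Without those 4 members the xenobiotic median was -0.41. Fatty acid oxidation genes fell in 11 of 23 cases and rose in none (0 rose and 11 fell when adjusted over the list alone; median log2 fold change -0.25, adjusted p = 0.0486, and adjusted p = 0.567 with an estimated correlation), with Acadm (-0.54) and Cpt1b (-0.56) as examples. Its median was -0.07 after cyclic loess, where it was not called (adjusted p = 0.239). That call also ended without control replicate 1 (adjusted p = 0.0521) or 3 (0.0876), without hydrogen replicate 2 (0.0748) or 3 (0.0704), and with array weights (0.0547), renewed quantile normalisation (0.185), the mean of all probe sets (0.0662), no shared probe sets (0.0955) or no dim rows (0.703).

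Genes of the heat shock response and the proteasome fell. Of 18 heat shock genes, 15 fell and none rose (0 rose and 15 fell when adjusted over the list alone; median log2 fold change -0.31, adjusted p = 0.000333, and adjusted p = 0.518 with an estimated correlation). The small heat shock protein gene Hspb1 fell the most of the examples, from 10.29 ± 0.23 to 9.16 ± 0.13 (SD, n = 3; limma adjusted p = 0.000286), followed by the chaperone genes Hspa4l (-0.61) and Hspa4 (-0.33). Of 30 proteasome genes, 18 fell and none rose (0 rose and 18 fell when adjusted over the list alone; median log2 fold change -0.25, adjusted p = 0.000333, and adjusted p = 0.518 with an estimated correlation), with Psmb7 (-0.78), Psmd14 (-0.46) and Psmc1 (-0.38) as examples. After cyclic loess the medians were -0.17 for heat shock genes (adjusted p = 0.0131) and -0.09 for proteasome genes, which were not called (adjusted p = 0.155). Neither list passed against random lists of like brightness (adjusted p = 0.0679 and 0.101). The list of the unfolded protein response of the endoplasmic reticulum was not called, with 2 rises and 6 falls among 22 genes (2 rose and 5 fell when adjusted over the list alone; adjusted p = 0.362). A further probe set of Hspb1 changed the opposite way, and with the mean of all probe sets Hspb1 was -0.45. After cyclic loess Hspa4 was -0.17, Psmc1 -0.20 and Psmd14 -0.30.

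Antioxidant genes showed no rise as a group. Of 28 targets of NRF2, the transcription factor that answers oxidative stress, 12 fell, none rose and 16 did not pass (0 rose and 10 fell when adjusted over the list alone; median log2 fold change -0.15, adjusted p = 0.0482, and adjusted p = 0.525 with an estimated correlation). The median was 0.02 after renewed quantile normalisation and 0.01 after cyclic loess, where the list was not called (adjusted p = 0.646 and 0.681). The glutathione synthesis genes Gclc (log2 fold change -0.68, SE 0.08, adjusted p = 0.000371) and Gclm (-0.50) fell, and Gclm was -0.30 after cyclic loess. Nqo1 fell slightly (-0.18, adjusted p = 0.0338), a call that was lost on leaving out control replicate 1, 2 or 3 or hydrogen replicate 2 or 3 (adjusted p = 0.0576, 0.0868, 0.0714, 0.12 and 0.0761), with a replicate block (0.0609) and with a trend and robust fitting in the prior variance (0.0649). Hmox1 had 0.14 (adjusted p = 0.135) and Cat 0.16 (adjusted p = 0.0763), neither past the threshold, with values of 0.07 for Hmox1 without hydrogen replicate 2 and 0.10 for Cat without control replicate 3. Cat was past the threshold after cyclic loess (0.23, adjusted p = 0.0299), after renewed quantile normalisation (0.22, adjusted p = 0.0381), without control replicate 1 (0.0281), with a trend and robust fitting in the prior variance (0.0252), with the mean of all probe sets (0.0134) and without shared probe sets (0.28, adjusted p = 0.00637). Over all alternatives the adjusted p of the list was 0.0105 to 0.767. The NRF2 call ended without control replicate 1 or 2 or hydrogen replicate 1 or 2 (adjusted p = 0.0819, 0.0776, 0.054 and 0.0565), with a replicate block (0.0606), a trend and robust fitting (0.0589) or the mean of all probe sets (0.067), and without shared probe sets (0.107) or dim rows (0.538). Of 24 other antioxidant enzymes, 9 fell and 1 rose (0 rose and 9 fell when adjusted over the list alone; median log2 fold change -0.12, adjusted p = 0.0297, and adjusted p = 0.518 with an estimated correlation), with the mitochondrial superoxide dismutase gene Sod2 (-0.49), Prdx4 (-0.42) and Mt1 (-0.93) lower, although a further probe set of Sod2 changed the opposite way. Mt1 was -0.00333 without shared probe sets, Sod2 -0.32 with the mean of all probe sets and Prdx4 -0.24 after cyclic loess. That list was not called without control replicate 3 (adjusted p = 0.0534) or after cyclic loess (median -0.03, adjusted p = 0.453), and its median was -0.21 without shared probe sets.

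Glucocorticoid-induced genes fell. Of 21 measured, 14 fell, 1 rose and 6 did not pass (1 rose and 14 fell when adjusted over the list alone; median log2 fold change -0.57, adjusted p = 0.00474, and adjusted p = 0.518 with an estimated correlation). The sulfotransferase gene Sult1a1 (log2 fold change -1.12, SE 0.17, adjusted p = 0.00131), the metallothionein gene Mt1 (-0.93) and the signalling inhibitor gene Errfi1 (-0.80) fell, while Hif3a rose (1.13, adjusted p = 0.00089). Mt1 was -0.00333 without shared probe sets (adjusted p = 0.971), and Hif3a 0.39 with the mean of all probe sets. The glucocorticoid list median was -0.50, -0.65 and -0.39 in hydrogen replicates 1, 2 and 3, relative to the controls. The list was not called without dim rows (adjusted p = 0.134). Of 18 clock genes, 6 fell, 1 rose and 11 did not pass (1 rose and 5 fell when adjusted over the list alone), and the list was not called (adjusted p = 0.259), although it was without hydrogen replicate 3 (median -0.43, adjusted p = 0.00421). The circadian repressor gene Cry1 (log2 fold change -1.76, SE 0.25, adjusted p = 0.000954) fell. The clock-output gene Dbp spread widely within both groups, with 5.96 ± 0.71 in controls and 7.41 ± 1.19 in the hydrogen group (SD, n = 3; adjusted p = 0.0516) and a log2 fold change of 1.45, or 0.82 without hydrogen replicate 3. Dbp was past the threshold after cyclic loess (1.62, adjusted p = 0.0447), after renewed quantile normalisation (0.044), without shared probe sets (0.0499), without control replicate 2 (0.0472) and without hydrogen replicate 1 (0.0136). The clock list median was -0.48 and -0.46 in hydrogen replicates 1 and 2 and 0.31 in replicate 3, relative to the controls.

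Cell cycle genes went both ways with more falling. Of 39 measured, 15 fell, 4 rose and 20 did not pass (4 rose and 15 fell when adjusted over the list alone; median log2 fold change -0.10, adjusted p = 0.0409, and adjusted p = 0.567 with an estimated correlation). The proliferation marker Mki67 (log2 fold change -1.20, SE 0.11, adjusted p = 0.000219), the ribonucleotide reductase gene Rrm2 (-0.92) and the replication licensing gene Cdc6 (-0.54) fell. The 4 that rose, named after their values were seen, were Foxm1 (0.73), Plk1 (0.37), Uhrf1 (0.25) and Aurka (0.20). The control means of Uhrf1 and Aurka were low (4.27 and 3.54). Top2a fell by 0.75 on its brightest probe set, whereas 2 further probe sets of the gene were higher, and its value was 0.24 without shared probe sets. With the mean of all probe sets Rrm2 was -0.46. The list median was -0.04 without shared probe sets, -0.05 with the mean of all probe sets and -0.16 after cyclic loess. The call ended without control replicate 1 or 3 or hydrogen replicate 1 (adjusted p = 0.0617, 0.0626 and 0.0794) without shared probe sets (0.246) or dim rows (0.576), with array weights (0.0551) and with the mean of all probe sets (0.0613), with a range of 0.000204 to 0.576 over the alternatives tried.

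Of the other lists past the threshold in the lower direction, smooth muscle and pericyte markers fell in 11 of 18 cases and rose in 2 (2 rose and 13 fell when adjusted over the list alone; median log2 fold change -0.29, adjusted p = 0.0192, and adjusted p = 0.518 with an estimated correlation), with Rgs5 (-1.12) and Myh11 (-0.71), of which the latter had a probe set that changed the opposite way. Collagen and matrix genes fell in 12 of 31 cases and rose in 2 (2 rose and 12 fell when adjusted over the list alone; median log2 fold change -0.14, adjusted p = 0.0192, and adjusted p = 0.518 with an estimated correlation), with Timp3 (-0.51) and P4ha2 (-0.71). Alveolar macrophage markers fell in 7 of 18 cases (0 rose and 7 fell when adjusted over the list alone; median log2 fold change -0.23, adjusted p = 0.0297, and adjusted p = 0.567 with an estimated correlation), among them Car4 (-0.57) and Ctsk (-0.78). Hypoxia-induced genes fell in 13 of 24 cases and rose in 2 (2 rose and 13 fell when adjusted over the list alone; median log2 fold change -0.24, adjusted p = 0.0297, and adjusted p = 0.518 with an estimated correlation), and glycolysis genes fell in 8 of 15 cases and rose in 1 (1 rose and 8 fell when adjusted over the list alone; median log2 fold change -0.24, adjusted p = 0.0297, and adjusted p = 0.518 with an estimated correlation). Both included the glucose transporter gene Slc2a1 (log2 fold change -1.19, SE 0.10, adjusted p = 0.000186) and the hexokinase gene Hk2 (-0.98). The p53 and apoptosis list had 11 falls among 22 genes (0 rose and 11 fell when adjusted over the list alone; median log2 fold change -0.15, adjusted p = 0.0409, and adjusted p = 0.518 with an estimated correlation), with Perp (-1.11) and Ccng1 (-0.58). RNA splicing factors fell in 9 of 35 cases and rose in 1 (1 rose and 8 fell when adjusted over the list alone; median log2 fold change -0.12, adjusted p = 0.0297, and adjusted p = 0.518 with an estimated correlation), and their median turned to 0.01 and 0.03 after quantile normalisation and cyclic loess. After cyclic loess the smooth muscle, collagen, hypoxia, glycolysis and p53 lists had medians of -0.20, -0.10, -0.08, -0.09 and -0.14 and were not called (adjusted p = 0.0771, 0.142, 0.239, 0.277 and 0.155). Without control replicate 3 the alveolar macrophage (adjusted p = 0.0876), hypoxia, glycolysis and p53 lists (0.0534 each) were not called. Without control replicate 1 the p53 (0.0599) and splicing (0.0611) lists were not called. The p53 call changed in 10 of 19 other settings. Without shared probe sets Slc2a1 was -0.19 (adjusted p = 0.0837) and Car4 -0.31, and with the mean of all probe sets Rgs5 was -0.25 and Myh11 -0.23.

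Of the 6 lists called upward, the T cell and B cell lists had 8 and 5 dim members of 19 each, while dim members made up 14 of 20 squamous, 8 of 12 thymocyte, 5 of 8 thyroid and 15 of 19 cartilage markers. Without dim rows the T cell and B cell lists stayed past the threshold (adjusted p = 0.000342 and 0.0405). Of 19 T cell markers, 11 rose and none fell (11 rose and 0 fell when adjusted over the list alone; median log2 fold change 0.20, adjusted p = 0.0026, and adjusted p = 0.518 with an estimated correlation), among them the surface receptor genes Cd6 (log2 fold change 0.70, SE 0.06, adjusted p = 0.000232), Cd8a (0.54) and Cd4 (0.34). The T cell median was 0.31 without control replicate 1, 0.34 without dim rows and 0.33 without shared probe sets. Of 19 B cell markers, 9 rose and 1 fell (9 rose and 1 fell when adjusted over the list alone; median log2 fold change 0.24, adjusted p = 0.034, and adjusted p = 0.593 with an estimated correlation), with Blk (0.43) and Cd22 (0.29), while Cd79a had 0.06 (adjusted p = 0.542), which was -0.02 after cyclic loess and -0.01 without control replicate 3. Of 12 thymocyte markers, 6 rose and none fell (6 rose and 0 fell when adjusted over the list alone; median log2 fold change 0.17, adjusted p = 0.0409, and adjusted p = 0.518 with an estimated correlation), including Dntt (0.34). Squamous epithelial markers rose in 12 of 20 cases and fell in 1 (12 rose and 1 fell when adjusted over the list alone; median log2 fold change 0.22, adjusted p = 0.0297, and adjusted p = 0.518 with an estimated correlation), led by the keratin genes Krt4 (0.77) and Krt6a (0.71). Thyroid markers rose in 4 of 8 cases (5 rose and 0 fell when adjusted over the list alone; median log2 fold change 0.15, adjusted p = 0.0481, and adjusted p = 0.518 with an estimated correlation), with Slc5a5 (0.52). Cartilage and tracheal gland markers rose in 10 of 19 cases and fell in 2 (10 rose and 2 fell when adjusted over the list alone; median log2 fold change 0.18, adjusted p = 0.0481, and adjusted p = 0.518 with an estimated correlation), with Col9a1 (0.70) and a mean of -0.002, opposite in sign to the median and the test. The lowest member of the cartilage and tracheal gland list was at -2.68, a larger change than its highest (0.70). The B cell call ended without control replicate 3 (0.101) or hydrogen replicate 2 (0.0719). The thymocyte, thyroid and cartilage calls each ended on leaving out any of at least 3 single arrays, at adjusted p values from 0.052 to 0.0821. Over 18 other settings these calls changed in 9, 12 and 11. After cyclic loess the B cell, thymocyte, squamous, thyroid and cartilage medians were 0.26, 0.11, 0.13, 0.06 and 0.08, and none of these lists was called (adjusted p = 0.0648, 0.276, 0.427, 0.331 and 0.681). None of the lists called upward passed against random lists of like brightness, where the T cell and squamous lists had an adjusted p of 0.358 and 0.267. Of the genes named here, Col9a1 was 0.05 without shared probe sets (adjusted p = 0.525), Cd22 was 0.09 with the mean of all probe sets (0.176) and Dntt was 0.22 after cyclic loess (0.0659). Cd8a was 0.31 with the mean of all probe sets, Krt6a 0.27 without shared probe sets and Blk 0.29 after cyclic loess.

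**Figure D4:**
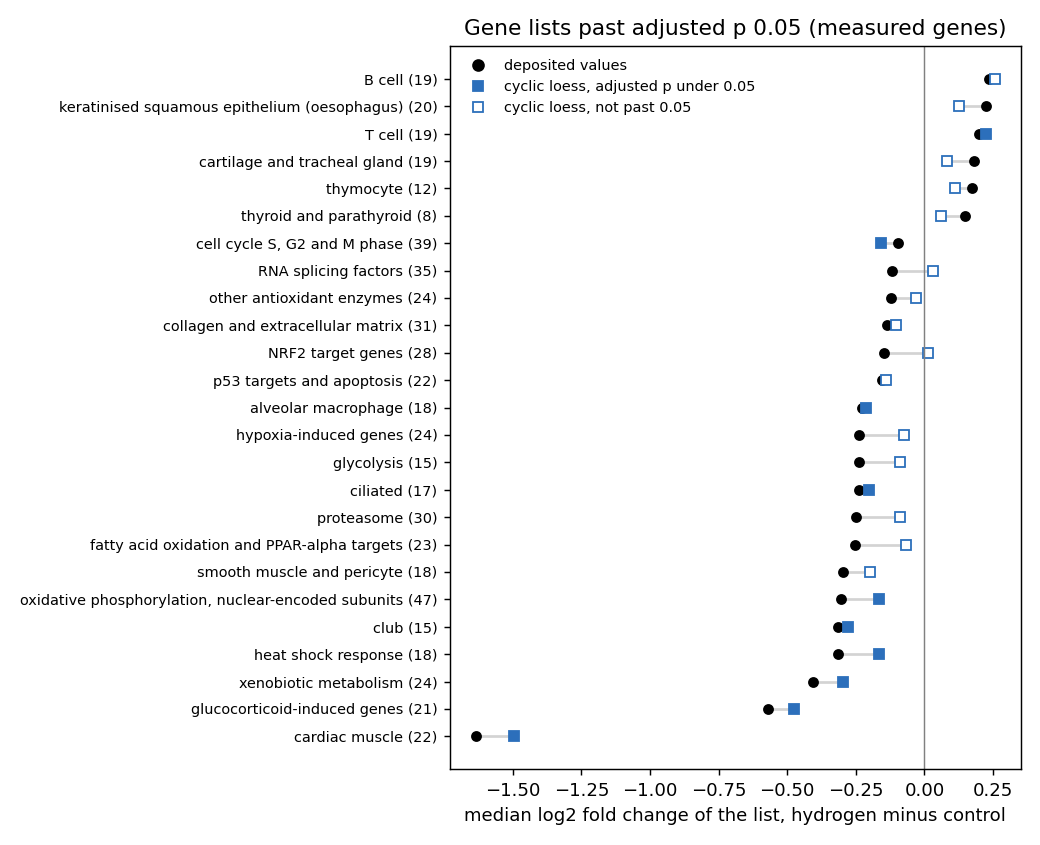
Median log2 fold change (hydrogen minus control) of the 25 gene lists past an adjusted p of 0.05 in camera, from the deposited values (circles) and after cyclic loess (squares, filled where the list was still past 0.05). The cardiac list lay at -1.63 and -1.49, 10 of the 25 lists were filled, and the NRF2 and RNA splicing medians turned from -0.15 and -0.12 to 0.01 and 0.03.

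The largest rises of single genes were smaller than the largest falls. They were the lysine methyltransferase gene Mettl21a (log2 fold change 1.34, SE 0.08, adjusted p = 0.000132), Nwd1 (log2 fold change 1.28, SE 0.09, adjusted p = 0.000186), Krtap5-1 (1.25), Dnajc17 (1.22), Grin2d (1.15), which encodes a glutamate receptor subunit, Slurp1 (1.15), Spon2 (1.15), Alb (1.15), which encodes albumin, Oxt (1.14), which encodes oxytocin, and Hif3a (1.13). Several were smaller on other probe sets: Mettl21a was 0.22 and Spon2 0.32 without shared probe sets, and Dnajc17 was 0.57 with the mean of all probe sets. A nonspecific control probe set, which matches no mouse gene, rose by 1.07, close to these largest rises. The GC content of the genes with the largest rises was not checked. Nos1, the neuronal nitric oxide synthase gene, rose (0.71, adjusted p = 0.000643), and was 0.33 with the mean of all probe sets. The surfactant gene Sftpc had 0.02 (adjusted p = 0.761) at a level of 13.15 and -0.07 after cyclic loess, the immediate early gene Fos -0.42 (adjusted p = 0.206) and the neutrophil gene S100a8 0.49 (adjusted p = 0.0693), none past the threshold. Fos was -0.14 without hydrogen replicate 2, -0.23 without control replicate 3 and -0.64 without control replicate 1, and -0.23 after cyclic loess. S100a8 was 0.26 without control replicate 3, and was past the threshold after cyclic loess (0.66, adjusted p = 0.0335), after renewed quantile normalisation (0.0324), with a replicate block (0.00541), without control replicate 2 (0.0426) and without hydrogen replicate 3 (0.0437). The collagen gene Col1a1 fell (-0.34, adjusted p = 0.00738).

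Across the 56 lists, 25 were past an adjusted p of 0.05 in camera with the preset correlation, 6 upward and 19 downward (1 and 9 after renewed quantile normalisation and also after cyclic loess), against up to 24 in another split of the 6 arrays, and none with an estimated correlation, where the lowest adjusted p was 0.518 and 3 lists had an unadjusted p under 0.05. With cyclic loess, 10 of the 25 remained past the threshold: the oxidative phosphorylation, xenobiotic, cardiac, glucocorticoid, club, cell cycle, ciliated, heat shock, alveolar macrophage and T cell lists. The same 10 lists were past it after renewed quantile normalisation. Without shared probe sets 10 of the 25 remained: the oxidative phosphorylation, xenobiotic, cardiac, glucocorticoid, club, heat shock, proteasome, splicing, other antioxidant and T cell lists. Without dim rows 22 of the 25 could be tested and 7 remained: the oxidative phosphorylation, xenobiotic, cardiac, heat shock, proteasome, T cell and B cell lists. In fry 34 of the 56 lists were past it, among them 22 of the 25. Against random lists of like brightness, 9 lists were past it, and 6 lists were past it there, in camera and after cyclic loess: oxidative phosphorylation, xenobiotic metabolism, cardiac muscle, glucocorticoid-induced, club and cell cycle. Of the 1115 distinct list members, 198 rose and 376 fell over all genes tested, and 197 rose and 374 fell when adjusted over the list members alone.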

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

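The tests weighing explanations in this part were chosen after the results were seen; the counts over other splits of the arrays were fixed beforehand.

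A control probe set of nonspecific probes with 25 G or C bases, outside the measurement of mouse genes, was higher by 1.07 (log2) in the hydrogen arrays. Of the 15588 probe sets without a gene name, 3778 were higher and 3014 lower in the hydrogen arrays at an adjusted p under 0.05 in limma.

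Of all genes, 52.5% passed the threshold between the groups. A trend of the fold change with brightness was not the whole cause, since 36.8% of genes were still past it after cyclic loess. A technical difference between the arrays in labelling or hybridisation is a candidate explanation, because 49.4% of probe sets of non-mouse origin passed too, and the groups may also have been normalised apart, because sorted values lay 9.08 times farther apart between groups than within them. The effect of hydrogen on broad expression stays open and untested, since each group may have been a batch of its own and the labels give no batch. That limit holds for every gene and list compared here, including the cardiac, airway and glucocorticoid ones below. With 10 splits no share under 0.05 can be reached: the real grouping gave 8970 genes (highest other split 0), 21213 probe sets (0), 10118 genes at an unadjusted p under 0.05 (385), 1124 genes changed at least 1.5-fold (24) and 25 gene lists (24), so 1 split in each case reached the real number.

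Cardiac muscle and airway secretory genes were lower in the hydrogen group. A brightness trend was argued against, as the cardiac median stayed at -1.49 after cyclic loess (adjusted p = 0.000155). A smaller share of heart or vein muscle in the hydrogen samples stays open: 18 of 19 cardiac markers bright in the controls (94.7%), of which 0 were in another list, lay below every control in all 3 hydrogen arrays, and one of them, Myl7, named after its values were seen, went from 11.01 to 8.84, but this restates the pattern and a fall within lung cells would give the same count. The test of an even loss did not decide either, since 16 of the 19 changes lay between -2.22 and -1.32 while all 19 spanned 4.63 (log2), with Nppa at -4.33 and Nkx2-5 at 0.30. Nkx2-5 had a control mean of 5.18, in a brightness decile with a median change of 0.10. For less large-airway tissue the test did not decide. Of 29 club and ciliated markers that were not dim, 19 fell (65.5%). That was above the 38.6% of all such genes but short of nearly all. Only an even loss would need nearly all of them, and a loss of some airways need not be even. The changes were uneven, with Bpifa1 at -4.44 and Scgb1a1, near the top of the scale, at 0.01. In the club list, 4 of the 15 markers were in another list. A change within lung cells under hydrogen stays open and untested.

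Glucocorticoid-induced genes were lower, and clock genes differed between mice of one group. A brightness trend was argued against, as the glucocorticoid median stayed at -0.48 after cyclic loess (adjusted p = 0.00876), although 10 of the 21 members were in another list. Differences in time of day or handling at sacrifice stay open: the clock list's median SD within groups was 0.41, at percentile 100 of 10000 random lists of like brightness, but this restates the pattern. Such a spread was not particular to clock genes, since the cardiac (0.54) and glucocorticoid (0.23) lists also lay at percentile 100 and the club list at 97.9. Time of day or handling could move glucocorticoid-induced genes too, so the spread of that list does not count against this explanation. An effect of hydrogen on these genes was not tested apart from this and stays open.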

How the results depend on the processing

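Tests with cyclic loess and with brightness-matched lists were chosen after the data were seen; the others were planned. The spread between arrays and the counts of genes and probe sets stayed within 1.5 times of their main values except as follows. Leaving out dim rows gave 5852 genes, 12059 probe sets and 6501 genes at an unadjusted p under 0.05, with fewer genes tested. The mean of all probe sets of a gene gave 713 genes changed at least 1.5-fold. Cyclic loess gave 6300 genes, of which 5081 were shared with the main 8970, all in the same direction. The number of gene lists past the threshold was 25 and became 10 with renewed quantile normalisation, 10 with cyclic loess, 10 without shared probe sets, 9 without dim rows, 9 against brightness-matched lists, 0 with an estimated correlation in camera, and 16 to 25 on leaving out single arrays (16 without control replicate 3). On leaving out single arrays the number of genes was 7052 to 8247. Top2a (0.24), Plet1 (0.64), Becn1 (0.00333) and Snx22 (0.06) changed sign without shared probe sets and Psmd4 (0.0822) with the mean of all probe sets; the list of other antioxidant enzymes lay 0.0117 above its brightness-matched lists. Of 153 named genes, 145 were past the threshold; 132 stayed so after quantile normalisation and 135 after cyclic loess, and Cat, Dbp and S100a8, which were not past it, passed after both. The medians of the NRF2 targets (0.02 and 0.01) and RNA splicing factors (0.01 and 0.03) turned positive with quantile normalisation and cyclic loess, without a call. The cause of these changes was not tested, except that fewer genes enter without dim rows. Nothing in the labels says that the replicate numbers pair the mice. Deviations of arrays with the same number correlated at 0.08, 0.03 and -0.13, against -0.13 to 0.11 for different numbers. This gave no sign of pairing but cannot exclude it. With a replicate block 8360 genes, 19777 probe sets and 21 lists were past the threshold. Low signal limits what dim genes show: 36.8% of genes lay at or below the median probe set of 4.80.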

Other observations

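The comparison with random lists of like brightness and the count of the most variable genes were chosen after the results were seen. Of 18 alveolar type 2 cell markers, 7 rose, 1 fell and 10 did not pass (7 rose and 1 fell when adjusted over the list alone), with a median log2 fold change of 0.11. Camera did not call the list (adjusted p = 0.131), nor did it after cyclic loess (median 0.24, adjusted p = 0.0509). The median of the deposited values exceeded random lists of like brightness (adjusted p = 0.00224). The transcription factor gene Etv5 rose (0.35, limma adjusted p = 0.00319). Mesothelial markers had 4 rises and 2 falls among 12 (median 0.18, adjusted p = 0.569 in camera and 0.0192 against like lists), and the median was -0.05 without control replicate 1, with Krt19 lower (-0.60, adjusted p = 0.000291). Cytosolic ribosomal protein genes had 3 rises and 0 falls among 41, and none when adjusted over the list alone (median 0.03, adjusted p = 0.583 and 0.0274). In camera with an estimated correlation the alveolar type 2, mesothelial and ribosomal lists had adjusted p = 0.567, 0.816 and 0.816.

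Lists that were not called held single genes past the threshold. Among inflammatory genes, 12 rose and 4 fell of 34, with the prostaglandin synthase gene Ptgs2 lower (-1.36, adjusted p = 0.000305). With the mean of all probe sets Ptgs2 was -0.65. Among interferon response genes, 6 rose and 9 fell of 32, with Oas2 higher (0.84, adjusted p = 0.000297). Among immediate early genes, 6 rose and 10 fell of 36. The Nr4a2 value there (-1.27, adjusted p = 0.000186) came from its brightest probe set, and 3 further probe sets of the gene were higher. Among adipocyte markers, 4 rose and 6 fell of 15. The fat hormone gene Adipoq was 7.23, 3.44 and 4.60 in hydrogen replicates 1, 2 and 3, against 7.52 ± 0.21 in controls (SD, n = 3). Its call (adjusted p = 0.0279) ended on leaving out any array except hydrogen replicate 1, with adjusted p values from 0.0565 to 0.08, and the log2 fold change was -1.60 without hydrogen replicate 2. The Adipoq call also ended with a trend and robust fitting in the prior variance (adjusted p = 0.137) and after renewed quantile normalisation (0.0511). Among plasma cell markers, the joining chain gene Jchain was lower (-1.09, adjusted p = 0.00133).

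Of the 40 genes with the largest SD among the hydrogen arrays, 11 were cardiac markers, 5 clock genes, 4 club cell markers, 3 glucocorticoid-induced genes, 3 genes of xenobiotic metabolism and 2 adipocyte markers, with some genes in more than 1 list, and 31 were in any of the 56 lists. After Bpifa1 the largest SD values were those of Car3 (2.58) and Fabp4 (2.38), named after their values were seen. In 32 of the 40 the lowest hydrogen value was in replicate 2, in 6 in replicate 1 and in 2 in replicate 3. Per2, a clock gene named after its values were seen, was 4.90, 5.28 and 7.41 in hydrogen replicates 1, 2 and 3 and 7.48 to 7.70 in the controls.

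The remaining lists were not called. Their adjusted p in camera was 0.11 for mast cells, basophils and eosinophils, 0.11 for fibroblasts, 0.116 for neutrophils, 0.118 for oxidase and nitric oxide synthase genes, 0.118 for fatty acid synthesis and 0.118 for alveolar type 1 cells. It was 0.135 for lymphatic endothelium, 0.191 for platelets, 0.206 for type 2 immune genes, 0.214 for cytotoxic cells, 0.31 for endothelium and 0.31 for mitochondrial biogenesis. On leaving out 1 array the neutrophil list (without hydrogen replicate 3, adjusted p = 0.0338) and the fatty acid synthesis list (without hydrogen replicate 1, adjusted p = 0.033) were called. Without dim rows the neutrophil (0.0405) and alveolar type 2 (0.0358) lists were called, and with the mean of all probe sets the alveolar type 1 list (0.0293). Higher values, from 0.332 to 0.599, were found for the other lists, among them cholesterol synthesis, antigen presentation, dendritic cells, erythroid cells, neurons, interstitial macrophages, autophagy and Wnt targets.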
